A study of Danio rerio with 4 samples.

How the data were processed

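Whole zebrafish embryos at 5 hpf (epiboly) and 10 hpf (end of gastrulation) were measured on 4 Agilent 2-colour arrays, which lay on 1 slide and were scanned once. Per the labels' protocols, ovulated oocytes had been microinjected with 8.3 ng of morpholino per embryo, RNA had been taken up in Trizol and labelled with a Quick-Amp kit. The labels name no injection for wild type. At each age, 1 array compared MO2 with 5m and 1 array MO2 with WT, with MO2 in Cy5 and the control in Cy3 throughout and no dye swap. The labels do not say whether the MO2 RNA of an age was 1 extract on both of its arrays, or whether any samples came from separate clutches.

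Per the file headers, the images had been read with Agilent Feature Extraction 10.5.1.1 and the probes placed on danRer5 (Zv7). The deposited value tables hold log10 ratios of Cy5 to Cy3 that the authors made with that software, after its background subtraction and dye normalization; they equalled the log ratio column of the scanner files on 100% of 45220 features within the checked tolerance, and each had a median of 0. The scanner files, as deposited, also hold linear spot and local background intensities, processed signals, a p-value of the log ratio from the software's error model, and marks for spots above background, saturated or uneven. Decimals were written with a comma and read as such.

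Spot means and local background medians were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1, with control spots at weight 0, under R 4.3.3 with the package data.table (1.17.8). Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Non-uniform outlier spots (19 to 58 per array) were left out. Spots with a local background above 3 times the array median (44 in all, 30 and 14 on the arrays of MO2 against WT at 5 hpf and against 5m at 10 hpf) were also left out, a choice made after the data had been seen. The reason was that they appeared to distort the normexp fit, which was not tested. The remaining spots of a probe were averaged. Values are log2 ratios of MO2 to control. For probes with 5 spots, the median SD between spots was 0.038 to 0.096, and the SD of all log2 ratios 0.30 to 0.50 per array.

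Probes were named from the RefSeq accession in the file (17327), the current symbol (1377) or a synonym (1261), and 23638 kept the name in the file; 18750 probes carried one of 12555 gene symbols. A gene is represented by its brightest probe. Other probes of a named gene, compared after the data had been seen, are given in the results on MO2, 5m and age where one was measured in the same samples and gave less than 0.5 of the named log2 value.

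Single arrays were summarised by a size rule, an absolute log2 ratio of at least 1 in probes above background, without a test. For MO2 against both controls, limma fitted 1 mean per age to the 4 arrays (2 residual degrees of freedom, prior 2.64) over 30313 probes well above background on at least 2 arrays, with Benjamini-Hochberg adjusted p under 0.05. The same fit tested the difference between ages. The 5m sample was compared with WT as the difference between the ratios of MO2 to each. Age in controls was tested with limma on the 4 Cy3 channels after Aquantile normalization (prior 2.28). For genes below background in all controls of an age, the fold is a bound against the background level. Tests were run on simulated data, in which limma recovered planted changes of 2-fold in 80.6% (5 hpf), 88.1% (10 hpf), 29.9% (difference between ages) and 23.9% (age in controls) of probes, and of 4-fold in 97.0% to 100%, with 9 to 20 calls that had not been planted. The simulated errors were independent between arrays, without a shared MO2 channel or dye bias. These rates therefore do not give the number of false calls in the tests on MO2.

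Fixed before the data were examined were the comparisons, the tests, most alternatives, the rule for naming genes and 24 gene lists. The lists were glucocorticoid receptor targets, the corticosteroid axis and steroidogenesis, the p53 response with morpholino off-target genes, apoptosis, BMP and the dorsoventral axis, Nodal signalling and mesendoderm, Wnt and FGF signalling, somitogenesis and presomitic mesoderm, neural plate and brain patterning, hox genes, the enveloping layer and epidermis, the hatching gland, the yolk syncytial layer, primordial germ cells and germ plasm, maternal transcripts of the egg, cell division and DNA replication, cell adhesion with matrix and gastrulation movements, blood and endothelium, muscle and heart structure, the heat shock, endoplasmic reticulum and early stress response, immune and inflammatory genes, the circadian clock, reference genes and cytosolic ribosomal proteins. A member counts as measured when it is above background in at least 1 channel. The percentile of a list median comes from 10000 random lists of the same size drawn from 20 brightness bins, for lists with at least 5 measured members. Of 165 percentiles, 46 lay above 97.5 and 16 below 2.5, where 8.25 were expected outside if members and comparisons were independent. The 7 comparisons include 5m against WT and age, and they share arrays. Members of a list can also vary together, so more can lie outside without an effect of MO2. A percentile describes these arrays and is no p-value.

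Named were nr3c1 first, then, per age, the 12 highest and 12 lowest genes at least 2-fold apart from both controls, ranked by the smaller ratio and measured in both channels. To these came the next 4 highest and lowest per array, the 6 highest and lowest of the difference between ages among those past the test, 4 each for 5m against WT, 6 each for age, and up to 4 members of each list and age by mean ratio. Identifiers of clones or predicted loci were counted and not named.

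Alternatives were the software's processed signals, the deposited value table, an offset of 0, median centring in place of loess, stricter and no filtering of dim probes, the software's p under 0.01 beside the size rule, an adjusted p under 0.1, control kind as a term, scaling of arrays to one spread, quantile normalization over all 8 channels, the MO2 channels for age, and each array left out. Added after the data had been seen were spots of bright background kept, all background outliers left out and the ribosomal list without S6 kinases. Also chosen then were the count of samples that stand apart, the overlap of 100 simulated data sets of 3 exchangeable samples, and the brightness-matched reading of median centring. Spike-in controls took no part in the comparisons.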

Results

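Transcripts of whole zebrafish embryos were measured on 4 2-colour arrays, at 5 and 10 hours post fertilization (hpf), during epiboly and at the end of gastrulation. On every array the Cy5 channel held RNA of embryos that had received MO2-nr3c1 (MO2), a morpholino, that is a synthetic antisense oligonucleotide, that blocks translation of the glucocorticoid receptor mRNA nr3c1. The Cy3 channel held a control of the same age, either embryos injected with a morpholino of the same sequence with 5 mismatches (5m) or wild-type embryos (WT), so that there was 1 array per age and control. The 4 arrays carried 43603 different probes, of which 57.9% to 59.1% lay well above background in both channels of an array. The median spot intensity was 29.9 to 33.8 in Cy3 over a local background of 12 to 13.5, and 133 to 158 in Cy5 over 54.5 to 57, and 0 spots were saturated. Each log2 ratio against 1 control had no replicate, and the number of arrays limits the precision of all values. Because MO2 was always in Cy5, a dye bias specific to a gene was part of each ratio of MO2 to a control.

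The targeted gene, nr3c1, was represented by 5 probes on chromosome 14 (Zv7 coordinates, per the file headers), 3 of which lay well above background in both channels of all 4 arrays. The brightest of these, A_15_P113183 (20795077 to 20795084), gave log2 ratios of MO2 to 5m of -0.21 at 5 hpf and -0.25 at 10 hpf, and of MO2 to WT of -0.72 at 5 hpf and 0.11 at 10 hpf. Probes A_15_P194346 (20796926 to 20796985) and A_15_P190681 (20796992 to 20797051) differed from 5m by -0.08 and -0.05 at 5 hpf and by -0.03 and -0.02 at 10 hpf. They were lower than WT at 5 hpf, by -0.50 and -0.60, and close to it at 10 hpf, at 0.08 for both. Against both controls the brightest probe did not pass limma's test at either age (5 hpf: log2 -0.47 ± 0.17 SE, adjusted p = 0.275; 10 hpf: -0.07 ± 0.17, adjusted p = 0.889). Probes A_15_P402780 (20795959 to 20796018, on the strand opposite to the other 4) and A_15_P190686 (20811433 to 20811492) were not well above background in both channels on any array. A morpholino that blocks translation need not lower its target mRNA, so the ratio of nr3c1 tests neither the knockdown nor the labels. Whether the probes lie in coding or untranslated sequence was not determined, since no annotation of Zv7 was used here.

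At 5 hpf, the transcripts that differed most from both controls were mainly higher in MO2 embryos. Chrna4b, a subunit of nicotinic acetylcholine receptors, was 14.2-fold higher (log2 mean of 2 arrays 3.82 ± 0.14 SE, adjusted p = 0.0234), and tamalin, a scaffold protein, 7.57-fold higher (2.92 ± 0.10, adjusted p = 0.0234). The SE is limma's, from the spread of all 4 arrays about the mean of their age. Gadd45aa, a DNA damage and growth arrest gene, was 8.95-fold higher, tnr, the matrix protein tenascin R, 7.02-fold, tcima 6.86-fold and slc1a4, a neutral amino acid transporter, 5.82-fold, although its second probe gave 0.93 and 0.29 where the first gave 2.72 and 2.36. Higher by log2 2.33 to 4.28 on each array and past the test were also phlda2, psme1, a subunit of the proteasome activator, and ifit8, of a family induced by interferon. Of the genes ranked with these, sp6 (3.04 against 5m and 4.68 against WT), metap2a (3.05 over both arrays) and fosab (2.32 and 3.34), which encodes a Fos subunit of the AP-1 transcription factor, did not pass (adjusted p = 0.0536, 0.237 and 0.0807).

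Lower at 5 hpf were mcm6, a subunit of the replicative helicase (5.15-fold, log2 -2.36 ± 0.19, adjusted p = 0.0456), stt3a, the catalytic subunit of oligosaccharyltransferase (4.09-fold, -2.03 ± 0.11, adjusted p = 0.0328), and lmnb1, the nuclear envelope protein lamin B1 (3.37-fold, -1.75 ± 0.10, adjusted p = 0.0328). Abcf2a, an ABC family protein, was 2.42-fold lower (adjusted p = 0.0470). With arrays centred on their median in place of loess, the ratios to 5m of lmnb1 and abcf2a turned to 0.01 and 0.48. They still lay 1.63 and 1.13 below the median of the 1000 probes nearest in brightness. A subset of the probes on that array then had a median of 0.70, while centring sets the median over its spots to 0. The ratio of abcf2a to WT turned to 0.28, against a median of 0.67 over a subset of the probes. The other genes ranked lowest did not pass. Their ratios to 5m and WT were -1.93 and -2.92 for grtp1a, -1.43 and -1.93 for uso1, a tethering factor of Golgi vesicles, and -1.40 and -1.63 for anxa2b, an annexin. They were -1.36 and -1.32 for calm3a, a calmodulin gene (its second probe -0.29 and -0.17), -1.28 and -1.55 for morc3b, -1.19 and -1.65 for erp44, which retains proteins in the endoplasmic reticulum, -1.17 and -1.97 for fyna, a Src family kinase, and -1.13 and -1.40 for stmn2a, a tubulin-binding protein. Against 5m, uso1, morc3b, erp44 and fyna also turned above 0 with median centring, 1.13 to 1.41 below the 1000 probes nearest in brightness.

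In the test against both controls at 5 hpf, 108 of 30313 probes were higher and 22 lower by limma at an adjusted p under 0.05. An unadjusted p under 0.05 was found for 5243 probes, where 1516 were expected by chance if the 2 ratios were independent. The 2 ratios share MO2 and its dye, so more can fall under 0.05 without any effect of MO2, and how many was not determined. By size alone, 230 probes were at least 2-fold higher on both arrays and 39 at least 2-fold lower. Independent lists would share 12.8 and 0.82, and simulated exchangeable samples that share the MO2 channel 163 and 164. The simulated spread of a probe came from these same arrays and held any real change. The simulated numbers are therefore not those of unchanged samples. The p-values set the mean of 2 arrays with different controls against a spread pooled over the pairs of both ages and limma's prior. They measure only how closely such pairs ran together, and no spread between replicate samples. The number of calls was 0 when any 1 of the 4 arrays was left out, with a normexp offset of 0, with the scanner software's processed signals, with the deposited value table and with spots of very bright background kept.

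Genes of the p53 response, fixed as a list because morpholinos can induce them off target, were the group furthest above both controls at 5 hpf. Of 15 measured members, 9 were at least 1.5-fold higher on both arrays and 0 lower. The list median was 0.89 against 5m and 1.39 against WT, each at percentile 100 of random lists matched on brightness. Over all probes 2 members passed, among them gadd45aa (log2 3.16 ± 0.20, adjusted p = 0.0343). When adjusted over the list alone, 10 were higher and 0 lower. Examples below the threshold over all probes were phlda3, an Akt repressor (2.06 against 5m and 4.37 against WT), bbc3, a killer of the Bcl2 family (1.98 and 3.71, its second probe 0.08 and 0.35), and mdm2, a ubiquitin ligase (1.74 and 3.15). In the apoptosis list, which also holds bbc3 and casp8, 4 of 30 measured members were 1.5-fold higher against both controls and 0 lower. Hdr, a death receptor gene, rose (1.43 ± 0.10, adjusted p = 0.0349). Adjusted over the list alone 2 members were higher and 0 lower. Of its other members, baxa, a pore-forming protein of mitochondria, was 0.60 above 5m and 1.14 above WT.

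Stress genes were higher as well. Of 26 measured members of the heat shock, endoplasmic reticulum and early stress list, 10 were 1.5-fold higher against both controls and 0 lower, with medians of 0.54 against 5m and 0.50 against WT (percentile 100 on both arrays, and 100 and 96.7 with median centring). Hmox1a, a heme oxygenase (4.62-fold, log2 2.21 ± 0.12, adjusted p = 0.0328), jun (3.39-fold, 1.76 ± 0.11, adjusted p = 0.0343) and gadd45bb (3.25-fold, 1.70 ± 0.11, adjusted p = 0.0343) passed over all probes, and 13 members, all higher, adjusted over the list alone. The heat shock gene hsp70l was 2.26 above 5m and 2.19 above WT without passing (adjusted p = 0.0920). Of 22 measured glucocorticoid receptor targets, 5 were 1.5-fold higher and 0 lower. Their median was 0.37 against 5m (percentile 99.9) and 0.22 against WT (percentile 93.7), which with median centring lay at percentiles 87.5 and 29.3. Of the members, 1 passed over all probes and 8, all higher, adjusted over the list alone. The member that passed was ddit4, a repressor of mTOR signalling (3.21-fold, 1.68 ± 0.09, adjusted p = 0.0328). Lnx1, a ubiquitin ligase, was 2.76 ± 0.37 above both controls, although its second probe, above background in both channels on 2 of the 4 arrays, gave 0.31 against 5m and 0.22 against WT, and anxa1a, an annexin, was 0.61 above 5m and 1.12 above WT (its second probe 0.16 and 0.68). Foxo3b, a transcription factor, was 1.64 above 5m and 3.41 above WT (its second probe 0.68 and 1.56). Of 13 measured genes of the corticosteroid axis and steroid synthesis, 1 was 1.5-fold higher, cyp11a1.1, the side chain cleavage enzyme (0.70 and 1.45). In all 0 passed, also when adjusted over the list alone, and the medians were 0.07 and 0.08.

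Among tissue and patterning lists at 5 hpf, the enveloping layer and epidermis list had 5 of 23 measured members 1.5-fold higher and 1 lower, with medians of 0.24 against 5m and 0.46 against WT (percentiles 97.8 and 100, and 92.9 and 99.99 with median centring). Over all probes 0 members passed, and adjusted over the list alone 7 were higher and 1 lower, for example cavin2b (1.27 and 1.51) and the keratin gene krt4 (0.87 and 1.14, its second probe -0.09 and 0.24). In the yolk syncytial layer list, tfa, which encodes transferrin, rose 3.39-fold (1.76 ± 0.11, adjusted p = 0.0343), 2 of 19 members were 1.5-fold higher and 5, all higher, passed adjusted over the list alone, with medians of 0.13 against 5m and 0.39 against WT (percentiles 83.9 and 99.9). Cell adhesion and gastrulation genes had 8 of 46 members 1.5-fold higher and 2 lower. Aplnrb, an apelin receptor (2.23 ± 0.14, adjusted p = 0.0343), and cldna, a claudin (1.71 ± 0.11, adjusted p = 0.0348), rose. Vangl2, a planar polarity gene, fell by 1.08 on the log2 scale (SE 0.10, adjusted p = 0.0475), although its second probe gave 0.07 against 5m and -0.22 against WT. Adjusted over the list alone 8 were higher and 2 lower. Mmp2, a gelatinase, was 2.12 above 5m and 3.94 above WT, and cxcl12b, a chemokine, 1.68 and 2.87 (its other probes 0.78 to 1.57), without passing. Of 29 maternal transcripts 1 rose, the cell cycle regulator rgcc (2.37-fold, adjusted p = 0.0470), which was also the only one adjusted over the list alone, and 0 fell. In the cell division list, mcm6 was the 1 of 35 members that passed over all probes. Among its members 1 was 1.5-fold higher and 2 lower, and 2 were higher and 2 lower adjusted over the list alone. The gene vangl2 lay outside the naming rule and was named after its values had been seen.

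The other lists had 0 members past the test over all probes at 5 hpf, apart from the cytosolic ribosomal proteins. Of these 82 measured genes, rps14 rose (1.24 ± 0.10, adjusted p = 0.0456), and 7 were 1.5-fold higher and 0 lower. Adjusted over the list alone 9, all higher, passed, with medians of 0.23 against 5m and 0.39 against WT. Members that passed adjusted over the list alone numbered 3 of 28 for BMP and the dorsoventral axis, 1 of 31 for Nodal signalling and mesendoderm, 1 of 34 for Wnt and FGF signalling and 1 of 4 for the hatching gland, all higher. They numbered 1 of 10 for blood and endothelium, 1 of 24 for immune genes, 2 of 18 for the circadian clock and 2 of 13 for the reference genes, all higher. For somitogenesis 1 of 26 was higher and 1 lower, for the neural plate 2 of 41 were higher and 1 lower. The counts were 0 of 14 for hox genes, 0 of 13 for muscle and heart structure and 0 of 12 for primordial germ cells. The reference gene actb1, a beta-actin, was 1.35 above 5m and 0.82 above WT, without passing.

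At 10 hpf, gadd45aa was 14.8-fold higher in MO2 than in both controls (log2 3.89 ± 0.20, adjusted p = 0.0400), gadd45bb 3.98-fold (1.99 ± 0.11, adjusted p = 0.0400), jun 2.91-fold (1.54 ± 0.11, adjusted p = 0.0418), hdr 3.35-fold (1.74 ± 0.10, adjusted p = 0.0400) and ripor3 6.60-fold (2.72 ± 0.20, adjusted p = 0.0433). Pglyrp6, a peptidoglycan recognition protein, was 5.59-fold higher and inka1a, a kinase inhibitor, 4.70-fold. Far above both controls without passing the test were fosab (3.04 against 5m and 4.45 against WT), phlda2 (3.12 and 3.41), rspo1, a Wnt agonist (2.90 and 4.09), and phlda3 (2.80 and 4.30). The same held for mdm2 (2.70 and 3.39), mmp2 (2.68 and 3.68), casp8, an initiator caspase (2.56 and 4.17), bbc3 (3.50 against WT), lnx1 (2.65 over both arrays, its second probe -0.09 and -0.15) and foxo3b (2.46 and 3.32). Their adjusted p lay between 0.0584 and 0.115.

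Lower at 10 hpf were mnd1 and psmc3ip, partners in meiotic recombination (4.08-fold and 3.57-fold lower, both with adjusted p = 0.0400), trmt44, a tRNA methyltransferase (6.03-fold, log2 -2.59 ± 0.16, adjusted p = 0.0400, but -0.88 by its second probe), and cpsf1, a subunit of the mRNA cleavage and polyadenylation complex (4.05-fold, -2.02 ± 0.10, adjusted p = 0.0400). Also lower and past the test were yy1b, a zinc finger transcription factor, ppiab, a cyclophilin, sirt2, a deacetylase, abcf2a and stt3a, by 3.07-fold to 3.66-fold. Anxa2b (-2.06 against 5m and -2.86 against WT), chaf1b, a chromatin assembly factor (-2.05 and -2.14), mcm6 (-1.82 and -2.15) and ivd, an enzyme of leucine breakdown (-2.10 and -1.58, with 1 of its 4 other probes at -0.87 and -0.74), did not pass.

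Over all probes, 38 were higher and 40 lower at 10 hpf by limma at an adjusted p under 0.05, of 5168 with an unadjusted p under 0.05. By size, 175 probes were 2-fold higher on both arrays and 77 lower, against 6.04 and 2.39 for independent lists. Simulated exchangeable samples that share the MO2 channel, whose spread held any real change, gave 154 and 153. The limma count fell to 0 under the same alternatives as at 5 hpf. With median centring it was 20171, of which 83.3% were higher in place of 48.7%. It was 193 (67.4% higher) with control kind as a term and 661 (59.8%) at an adjusted p under 0.1. With both channels above background it was 160 (58.8%). Without these alternatives, 21 of the probes called were higher and 6 lower at both ages, and 181 were called at either age. By size, 83 probes were 2-fold higher on all 4 arrays and 12 lower.

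By list at 10 hpf, 10 of 15 p53 response genes were 1.5-fold higher against both controls and 0 lower, with medians of 1.53 against 5m and 2.06 against WT (percentile 100 on both arrays). Gadd45aa was the 1 member that passed over all probes, and adjusted over the list alone 11 were higher and 0 lower. Of 28 apoptosis genes, 6 were 1.5-fold higher, 1 passed over all probes (hdr), and 9 were higher and 1 lower adjusted over the list alone. Ribosomal protein genes moved as a group. Of 82 measured, 40 were 1.5-fold higher on both arrays and 0 lower, with medians of 0.58 and 0.78 (percentile 100 on both arrays). Over all probes, rpl8 (1.74 ± 0.13, adjusted p = 0.0433, but 0.58 by its second probe) and rps14 (1.44 ± 0.10, adjusted p = 0.0418) passed, and 67 were higher and 0 lower adjusted over the list alone; rps27a was 1.40 above 5m and 1.63 above WT. The list's name pattern also takes kinases of ribosomal protein S6, without which the medians were 0.60 and 0.84. In the stress list, gadd45bb and jun passed over all probes, 5 of 27 members were 1.5-fold higher and 0 lower, and 10 were higher and 1 lower adjusted over the list alone. Its medians were 0.29 against 5m and 0.18 against WT (percentiles 100 and 93.7, and 99.99 and 54.1 with median centring). Hsp90ab1, a cytosolic chaperone, was at least 1.09 above each control by its brightest probe, while its 3 other probes lay between -0.15 and 0.22.

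Cell division genes lay below the controls at 10 hpf, with medians of -0.28 against 5m and -0.50 against WT (percentile 0 on both arrays). With median centring the medians were 0.92 and 0.86, against 0.50 and 0.52 over a subset of the probes. The list medians still lay at percentiles 0.01 and 0 of random lists of the same brightness. Of 35 measured members, 3 were 1.5-fold lower and 0 higher, and 0 passed over all probes. In all, 12 were lower and 1 higher adjusted over the list alone, among them ccne1, a cyclin (-0.82 against 5m and -1.55 against WT). Of the reference genes, sdha, a subunit of succinate dehydrogenase, fell (-1.64 ± 0.12, adjusted p = 0.0433), while adjusted over the list alone 3 of 13 were higher and 1 lower. Glucocorticoid receptor targets had medians of 0.10 and 0.26 (percentiles 88.9 and 95.6, and 80.5 and 99.3 with median centring), 2 of 22 members 1.5-fold higher, 0 past the test over all probes, and 3 higher and 1 lower adjusted over the list alone. Mt2, a metallothionein, was -0.54 against 5m and -1.06 against WT (its second probe 0.01 and 0.04). With median centring the ratio to WT turned above 0, 1.02 below the 1000 probes nearest in brightness. The corticosteroid list had 0 of 11 members past the test, also adjusted over the list alone, with medians of -0.08 and 0.10.

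The remaining lists had 0 members past the test over all probes at 10 hpf. Adjusted over the list alone, 7 enveloping layer genes of 25 were higher and 2 lower, 6 cell adhesion genes of 47 were higher and 1 lower, and 3 neural plate genes of 43 were higher and 2 lower. Likewise, 3 yolk syncytial layer genes of 19, 1 BMP gene of 29 and 1 muscle gene of 13 were higher. The counts were 0 of 29 for Nodal, 0 of 34 for Wnt and FGF, 0 of 30 for somitogenesis, 0 of 31 for hox, 0 of 6 for the hatching gland, 0 of 12 for germ cells, 0 of 29 for maternal transcripts, 0 of 9 for blood, 0 of 22 for immune genes and 0 of 18 for the circadian clock. Epcam, an adhesion molecule of epithelia, was -0.34 against 5m and -2.20 against WT, and mxtx2, a regulator of the yolk syncytial layer, was 1.59 and 1.27 above them. Hox genes had a median of 0.07 against 5m and 0.59 against WT (percentiles 91.8 and 100). Somitogenesis genes had medians of 0.16 and 0.45 (percentiles 99.5 and 100, and 100 on both arrays with median centring). Neural plate genes had a median of -0.11 against 5m (percentile 0.18), which turned to 0.83 (percentile 65.4) with median centring. Against WT their median was 0.21 (percentile 99.3).

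**Figure D1:**
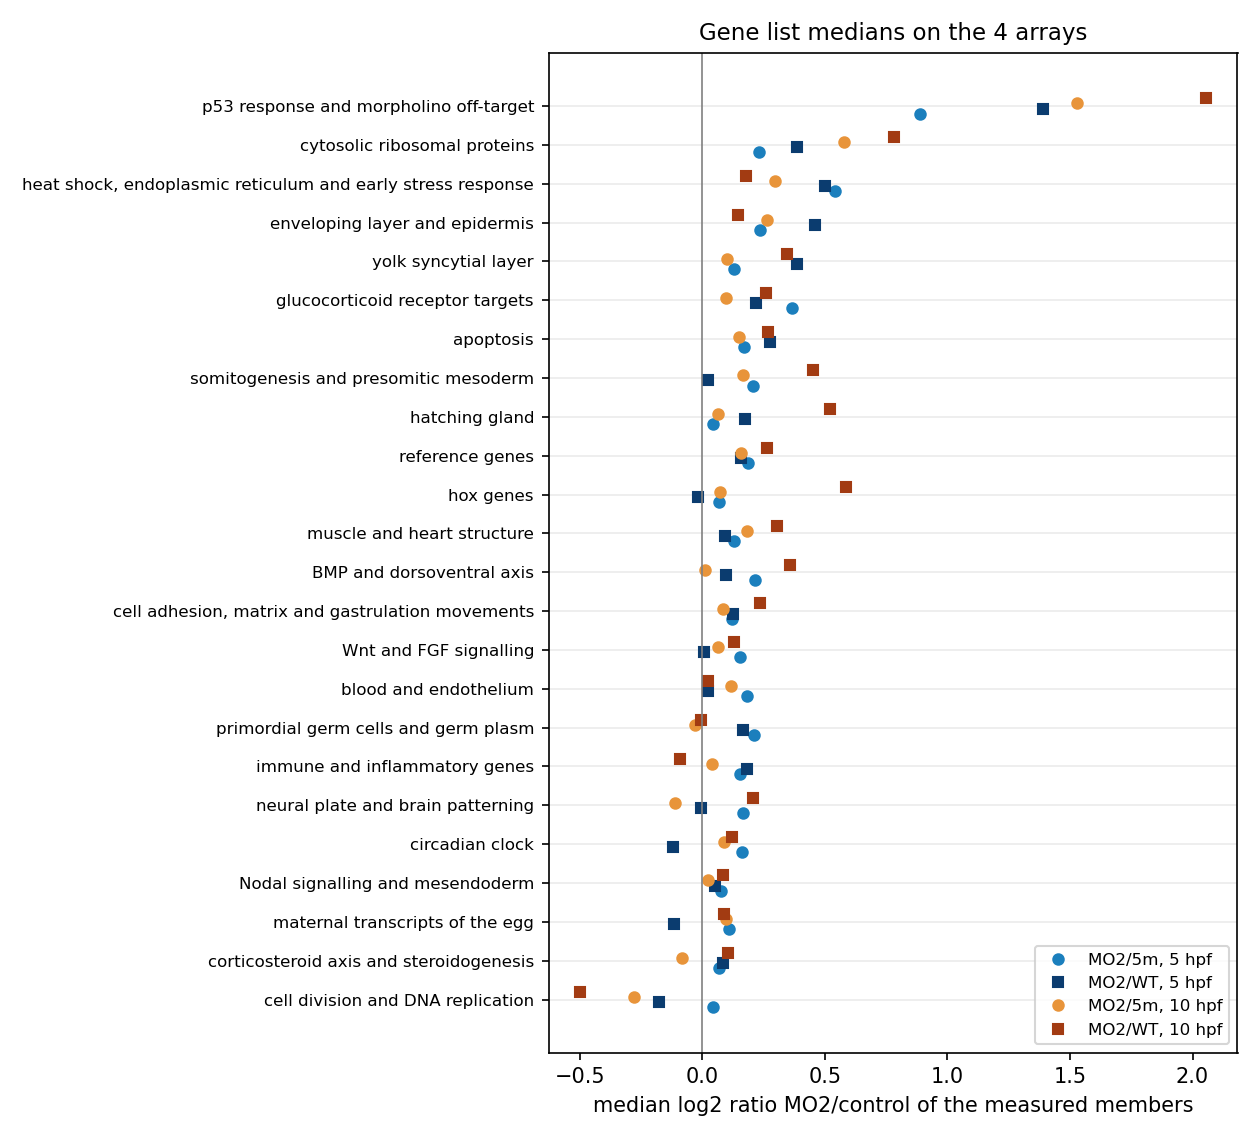
Median log2 ratio of MO2 to its control for the measured members of each of 24 gene lists (vertical axis), 1 point per array, with circles for 5m and squares for WT as control and blue for 5 hpf and orange to brown for 10 hpf. The p53 response list lies highest on all 4 arrays, at 0.89 to 2.06, and the cell division list lowest at 10 hpf, at -0.28 and -0.50, which turned above 0 (0.92 and 0.86) with median centring. Those 2 medians still lay at percentiles 0.01 and 0 of random lists of the same brightness.

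Against single controls, the number of probes at least 2-fold apart was 439 higher and 83 lower for MO2 against 5m at 5 hpf (28728 probes, 84.1% of the differences higher) and 831 higher and 291 lower against WT (29213 probes, 74.1%). At 10 hpf it was 204 higher and 117 lower against 5m (28754 probes, 63.6%) and 813 higher and 595 lower against WT (27965 probes, 57.7%). With median centring 99.9%, 99.5%, 99.8% and 98.3% of the differences were higher. A subset of the probes then had medians of 0.70, 0.67, 0.50 and 0.52. Centring sets the median over the spots of an array to 0, so these are not medians of whole arrays. Genes that stood out on single arrays included xylb, a xylulokinase gene (3.44 against 5m at 5 hpf), and c6.2, a complement component, which was higher on that array (2.70) and lower against WT at 10 hpf (-3.25). Slc4a2a, an anion exchanger, was 4.22 above WT at 5 hpf and 2.90 at 10 hpf, next to 2.28 and 2.32 above 5m, with other probes at 0.76 to 1.99 on the 4 arrays. Lower than 5m at 5 hpf were gle1, an mRNA export factor (-1.33), pabpn1, a poly(A)-binding protein (-1.25, its other probes -0.58 and -0.10), cmtr1, a cap methyltransferase (-1.21, its second probe -0.19), and zp3e, an egg coat gene (-1.19). The last 3 turned above 0 with median centring (0.38, 0.36 and 0.02), 1.18 to 1.24 below the 1000 probes nearest in brightness. Lower than WT at 5 hpf were quob (-2.62), f13a1b, a coagulation factor (-2.56), and npl, a sialic acid lyase (-2.35). At 10 hpf, pde6c, a phosphodiesterase (2.37), and rxrba, a retinoid X receptor (2.33, its other probes 0.50 and 0.86), were higher than 5m. In turn, sgsh, a lysosomal sulfamidase (-1.64), pemt, a phospholipid methyltransferase (-1.57), and chek2, a checkpoint kinase (-1.56), were lower. Against WT at 10 hpf, cfap100, a cilium protein (3.32), supt3h (3.09) and capgb, an actin capping protein (2.94), were higher. The lowest there were pde9ab (-3.43), panx1a, a pannexin channel (-2.97, its second probe 0.12), and neff1 (-2.86).

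**Figure D2:**
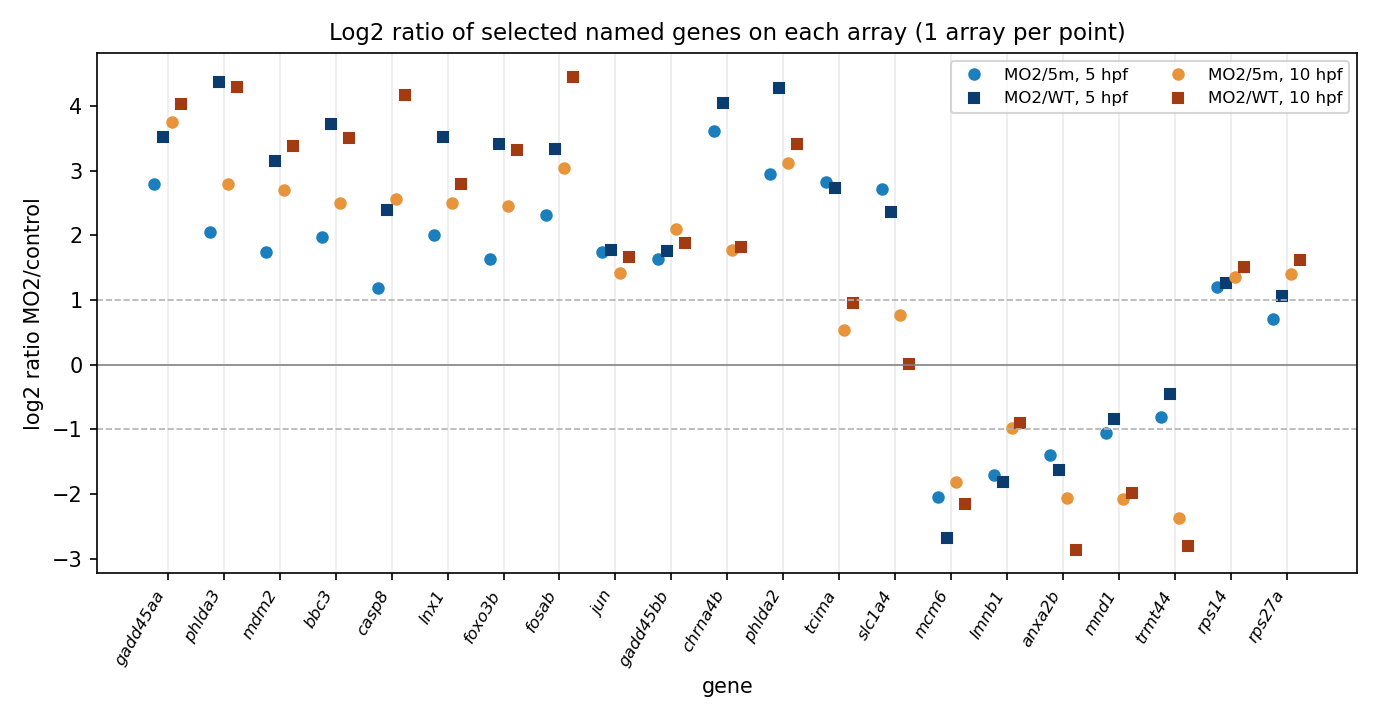
Log2 ratio of MO2 to its control for 21 of the named genes (horizontal axis), 1 point per array, with circles for 5m and squares for WT as control, blue for 5 hpf and orange to brown for 10 hpf, and dashed lines at 2-fold. Gadd45aa lies between 2.80 and 4.03 on all 4 arrays and mcm6 between -2.68 and -1.82, while slc1a4 lies at 2.72 and 2.36 at 5 hpf and at 0.77 and 0.01 at 10 hpf. The ratio of lmnb1 to 5m at 5 hpf turned to 0.01 with median centring, 1.63 below the median of the 1000 probes nearest in brightness.

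Whether the response to MO2 differed between 10 and 5 hpf was tested as the difference between the ratios of the 2 ages, in which a constant dye bias cancels. By limma, 0 of 30313 probes passed, with a smallest adjusted p of 0.302. An unadjusted p under 0.05 was found for 2559 probes, where 1516 were expected by chance if the ratios were independent. The 2 ratios of an age share MO2, so this expectation may be too low. Tcima, tnr and slc1a4 passed at 5 hpf but not at 10 hpf, and trmt44, cpsf1 and sirt2 at 10 hpf but not at 5 hpf. None of these genes was shown to differ between the ages. In simulated arrays with independent errors, differences of 4-fold were recovered for 97.0% of planted probes and of 2-fold for 29.9%. Under that model, smaller differences lay mostly out of reach. With median centring 4259 probes passed, 1495 higher and 2764 lower at 10 hpf.

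The 2 controls were compared through the MO2 channel. This gives the difference between mismatch-injected and wild-type embryos only if the MO2 RNA of an age was the same on both arrays. The labels do not state that, and a difference between MO2 extracts would be part of each value. Genes of the p53 response were higher in 5m than in WT, with list medians of 0.72 at 5 hpf and 0.53 at 10 hpf (percentile 100 at both ages), for example mdm2 (1.40 and 0.69), gadd45aa (0.72 and 0.27) and casp8 (1.21 and 1.60). Cell division genes were lower, with medians of -0.24 and -0.30 (percentile 0 at both ages), and ribosomal protein genes higher, with 0.15 and 0.28 (percentiles 99.99 and 100). At 10 hpf, hox genes lay 0.42 above WT (percentile 100) and somitogenesis genes 0.22 (percentile 99.4), for example hoxc8a (0.81) and her12, a segmentation clock gene (1.73). In this comparison, 13 of 31 measured hox genes were at least 1.5-fold higher than in WT in both 5m and MO2. At 5 hpf the median of hox genes was -0.09 and of somitogenesis genes -0.10 (percentiles 25.5 and 13.4). Receptor targets had medians of -0.01 and 0.08, with 2 of 22 members 1.5-fold higher in 5m and 4 lower at 5 hpf, and 6 higher and 1 lower at 10 hpf.

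Single genes far apart between the controls at 5 hpf were calr, a calcium-binding chaperone (5.04 higher in 5m, but 0.50 by its second probe), slc1a3a, a glutamate transporter (4.78), ndrg1b (4.14) and paqr3a (4.12). Lower in 5m were dnmt1, the maintenance DNA methyltransferase (-7.25), rrm2b, a ribonucleotide reductase subunit (-3.93), f13a1b (-3.27) and xylb (-3.19). The second probe of dnmt1 gave -0.19 against 5m and -0.75 against WT, where the first gave 4.59 and -2.66. At 10 hpf they were metap2a, a methionine aminopeptidase (4.22), supt3h (3.26), cfap100 (3.15) and capgb (2.76). Lower then were neff1 (-2.92), fat3a, a protocadherin (-2.69), panx1a (-2.60, but -0.05 by its second probe) and anxa2a, an annexin (-2.53). In all, 528 of 28241 probes were 2-fold higher in 5m and 479 lower at 5 hpf, and 399 and 359 of 27399 at 10 hpf. These differences were not tested, since each holds the error of 2 arrays and no replicate. With median centring the share of higher probes at 10 hpf was 65.9% in place of 52.6%, and with spots of very bright background kept the share at 5 hpf was 41.2% in place of 52.4%.

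The 3 kinds of embryo did not stand apart equally often. At 5 hpf, MO2 was 2-fold apart from both others, in one direction, for 269 probes, WT for 512 (151 higher and 361 lower) and 5m for 6 higher and 99 lower. At 10 hpf these numbers were 252 for MO2, 567 for WT and 8 for 5m. An error on the array of a control alone can set that control apart, while MO2 counts only where both arrays show it. The SD of log2 ratios was 0.46 (5 hpf) and 0.50 (10 hpf) on the WT arrays, and 0.35 and 0.30 on those with 5m. The counts of the 3 kinds are therefore not like for like. Across 22208 probes the ratios to 5m and WT of one age correlated at r = 0.457 (5 hpf) and 0.586 (10 hpf). Ratios of different ages share no sample. Between the ages, r was 0.467 for the ratios to 5m and 0.478 for those to WT. It was 0.426 for WT at 5 hpf with 5m at 10 hpf, and 0.329 for 5m at 5 hpf with WT at 10 hpf. A constant dye bias is part of these values too. Simulated exchangeable samples that share the MO2 channel gave an r within an age of 0.496 and 0.501 in the 28241 and 27399 probes of each age. There the observed r was 0.433 and 0.563, and the covariance 0.0703 and 0.0854 against a simulated 0.0892 and 0.0862. The simulated spread of a probe held any real change, so these values do not stand for unchanged samples. The correlations are across probes, which are not independent replicates.

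Between 5 and 10 hpf, control embryos changed in a large share of their transcripts, from genes of the egg and the blastula to genes of the body axis. Among the highest were cdx1a, which patterns the trunk (186-fold, log2 7.54 ± 0.44), otx2b, a head selector gene (97.9-fold), and myf5, a muscle determination gene (77.6-fold). Hoxb1b, a hox gene, meis2b, a hox cofactor, and fabp2, a fatty acid-binding protein, also rose. They were well above background on only 1 of the 2 control arrays of 5 hpf, so that no fold is given. The cyclin gene ccna1 fell (48.7-fold, -5.61 ± 0.23), with mxtx2 (46.7-fold), mixl1, an endoderm regulator (46.6-fold), ndr1, a Nodal ligand (37.0-fold), morc3b (35.1-fold) and tatdn2 (35.0-fold). All 12 had adjusted p between 0.00169 and 0.00253. Other probes gave log2 differences of 2.95 for cdx1a, 1.67 for fabp2, 2.27 in the lowest for meis2b and 1.97 in the lowest for otx2b. The brightest probe of nr3c1 rose (log2 1.999 ± 0.229, adjusted p = 0.00599).

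By list, 19 of 29 measured maternal transcripts of the egg fell with age and 2 rose (adjusted over the list alone 21 and 2), with a median of -2.34, for example zglp1 (-3.93 ± 0.25), the claudin gene cldnd (-4.33 ± 0.20) and bmp15, an oocyte growth factor (-2.45 ± 0.30). Of 12 germ cell genes 8 fell and 0 rose (9 and 0 adjusted over the list alone), among them piwil1 and piwil2, of the piRNA pathway (-2.27 ± 0.59 and -1.76 ± 0.23). Of 31 Nodal genes 13 fell and 6 rose (14 and 7). Neural plate genes rose in 29 of 45 and fell in 3 (29 and 3), with her9 at 5.18 ± 0.51 and neurog1 at 2.71 ± 0.43. Hox genes rose in 22 of 33 and fell in 1 (23 and 1), and somitogenesis genes rose in 20 of 30 and fell in 3 (20 and 5). Of 19 yolk syncytial layer genes 11 rose and 2 fell (11 and 2), among them tfa (4.21 ± 0.15) and apoa2, an apolipoprotein (3.83 ± 0.42). Of 35 Wnt and FGF genes 18 rose and 4 fell (19 and 6). Hsd11b2, which inactivates cortisol, was not well above background in either control of 5 hpf and was at least 5.10-fold higher at 10 hpf (adjusted p = 0.00724).

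In the other lists the numbers that rose and fell with age were 6 and 6 of 22 receptor targets (7 and 8 adjusted over the list alone), 4 and 2 of 13 corticosteroid genes (5 and 2), 2 and 2 of 15 p53 response genes (2 and 1), and 5 and 10 of 30 apoptosis genes (5 and 10). They were 9 and 6 of 29 BMP genes (12 and 8), 7 and 1 of 25 enveloping layer genes (6 and 1) and 1 and 1 of 6 hatching gland genes (1 and 1). They were 6 and 7 of 35 cell division genes (6 and 7), 18 and 13 of 47 adhesion genes (18 and 13), 2 and 2 of 11 blood genes (1 and 1), 4 and 0 of 14 muscle genes (3 and 0) and 8 and 5 of 27 stress genes (8 and 6). For immune genes they were 2 and 9 of 24 (5 and 10), for the circadian clock 4 and 3 of 19 (5 and 3), for reference genes 2 and 2 of 13 (2 and 2) and for ribosomal proteins 22 and 4 of 83 (18 and 4). Over all probes, 6146 of 30313 rose and 5957 fell by limma at an adjusted p under 0.05, with 15463 at an unadjusted p under 0.05. The count lay between 7259 and 8262 when 1 of the 4 arrays was left out, the lowest without the WT array of 5 hpf. The samples of an age were 1 5m and 1 WT sample, so that the spread behind these p-values held the difference between the control kinds.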

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

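The values in this part were picked out because the effects at 5 and 10 hpf had opposite signs and each passed a size limit, or because a signal appeared in spots that no comparison used.

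In 5m against WT, the lists past the lower limit of random lists at 5 hpf and past the upper one at 10 hpf were BMP and the dorsoventral axis (median log2 -0.21 at percentile 0.21, and 0.33 at percentile 100) and the neural plate (-0.15 at percentile 2.31, and 0.24 at percentile 99.95). Other lists also had medians of opposite signs, such as hox genes (-0.09 and 0.42), without passing these limits at both ages. Among genes named for 5m against WT, those at least 1.5-fold apart in opposite directions were calr (5.04 at 5 hpf and -0.71 at 10 hpf) and ndrg1b (4.14 and -1.51). The value of calr at 5 hpf rests on 1 probe, as its second gave 0.50. Each value came from 2 arrays without a replicate, so the differences between the ages were not tested.

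The 10 spike-in controls, synthetic transcripts added to the RNA, gave a mean log2 ratio 0.646 higher at 10 than at 5 hpf (SD 0.132 over the controls) with loess and 0.263 higher with median centring, with 10 of 10 lower at 5 hpf. The difference was not tested, and the cause was not tested.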

How the results depend on the processing

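The alternatives that keep bright-background spots, leave out all background outliers or drop the S6 kinases, and the comparison with probes of equal brightness, were tests chosen after the results had been seen. Across alternatives, 54 counts of comparisons stayed within 1.5 times their value and 55 did not. Counts of 0 that remained 0 are among those that stayed. Of list medians, 266 stayed within their spread, 118 moved and 4 reversed, and of values of named genes 728 stayed, 1856 moved and 20 reversed. A named gene counted as moved from a shift of the array's median SD between spots (0.038 to 0.096), a narrow limit. Median centring gave 836 of these. Processed signals and the value table come from the same software. These totals therefore do not measure stability. No paired analysis was possible because no number or clutch links the samples.

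Probes at least 2-fold apart from 5m at 5 hpf numbered 522, and 2647 with the software's processed signals, 2633 with the value table, 1435 with offset 0 and 11761 with median centring. Against WT at 5 hpf they numbered 1122, and under the same alternatives 4162, 4148, 2405 and 11469, and 388 with bright-background spots kept. Against 5m at 10 hpf they were 321, then 1593, 1585, 696 and 6567, and 143 with those spots kept. Against WT at 10 hpf they were 1408, then 4545, 4525, 3038 and 8899. For 5m against WT they were 1007 at 5 hpf, then 3979, 3981 and 2490, and 485 with bright-background spots kept, and 758 at 10 hpf, then 3263, 3268 and 2055. An offset shrinks ratios of dim probes by construction, so a smaller offset gives more calls; for the other alternatives the cause was not tested.

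For MO2 against both controls, limma called 130 probes at 5 hpf and 78 at 10 hpf. Both counts were 0 with processed signals, offset 0, the value table, bright-background spots kept, and with each of the 4 arrays left out (0 to 0), where the lone array of an age is assumed to vary like the others. At an unadjusted p under 0.05, limma then still gave 3083 to 4828 probes at 5 hpf and 1875 to 5492 at 10 hpf, and the smallest adjusted p lay between 0.0552 and 0.293 and between 0.0761 and 0.530. They were 74 and 47 without a filter on dim probes, 752 (70.7% higher in place of 83.1%) and 661 (59.8% in place of 48.7%) at an adjusted p under 0.1, 198 and 193 (67.4% higher) with control kind as a term, and 23671 and 20171 with median centring. With both channels above background, 160 were called at 10 hpf (58.8% higher). The difference between the ages gave 0 limma calls with each alternative run (1224 to 3549 probes at an unadjusted p under 0.05) except median centring, which gave 4259. The 12103 calls for age in controls became 7259 to 8262 with 1 array left out (7640 and 7259 without the 5m and WT arrays of 5 hpf, 7596 and 8262 without those of 10 hpf) and 25466 in the MO2 channels. A higher threshold gives more calls by construction; the cause was not tested for the others.

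Reversals all came with median centring. In a subset of the probes, the medians with loess were 0.02, 0.03, 0.02 and 0.01. With median centring they were 0.70 (5m, 5 hpf), 0.67 (WT, 5 hpf), 0.50 (5m, 10 hpf) and 0.52 (WT, 10 hpf). Which probes form this subset is not given here. It is not the whole array, since centring sets the median over its spots to 0. Against 5m at 5 hpf, values turned to 0.0139 for lmnb1, 0.0874 for uso1, 0.13 for morc3b, 0.43 for erp44, 0.48 for abcf2a, 0.29 for fyna, 0.38 for pabpn1, 0.36 for cmtr1 and 0.0190 for zp3e. Against WT at 5 hpf they turned to 0.28 for abcf2a, 0.18 for rrm2b, 0.0775 for slbp2 and 0.56 for cdc25b, and against 5m at 10 hpf to 0.0753 for pabpn1. Against WT at 10 hpf they turned to 0.00992 for chek2, 0.13 for mt2, 0.49 for cldne, 0.46 for cdca8, 0.41 for cdc20 and 0.0645 for tjp3. All 20 stayed below the median of that subset of probes, by 0.03 to 0.68, and below the 1000 probes nearest in brightness, by 0.98 to 1.63. The list medians that reversed were those of the neural plate against 5m at 10 hpf (0.83) and of cell division against WT at 5 hpf (1.51), 5m at 10 hpf (0.92) and WT at 10 hpf (0.86). Among random lists of the same brightness these lay at percentiles 65.4, 2.08, 0.01 and 0. The p53 response list lay at percentile 100 on all 4 arrays with median centring, and hox genes at 0.01 and 0 at 5 hpf and 100 on both arrays of 10 hpf. Of 30 list percentiles past the upper limit, 21 stayed past it with median centring, and of 4 past the lower limit 3 did. Of those between the limits, 10 moved above the upper limit and 6 below the lower one. Receptor targets against 5m at 5 hpf moved from 99.9 to 87.5. With the median over all probes of a gene in place of its brightest, the p53 response medians were 0.88, 1.14, 1.53 and 2.06.

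Signal over background limits what can be seen: 57.9% to 59.1% of probes lay well above background in both channels. All arrays lay on 1 slide, so no slide term applied.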

Other observations

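The tests of dye bias and of injection with dye bias, those of brightness bias and of spot flaws, and the offset of 0 in the test of stage, were chosen after the results they concern had been seen.

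Genes of the p53 response were higher in MO2 than in both controls at both ages, and higher in 5m than in WT. Dye bias is argued against only for the part between 5m and WT, in which it cancels and the lower of the list medians was 0.53. For the ratios of MO2 to 5m it stays open, together with injection of any morpholino. With a constant dye bias, these would predict the same ratio to 5m at both ages. The median ratio to 5m was 0.475 higher at 10 than at 5 hpf over 15 members, at percentile 100 of random lists. This rests on 1 array per age without a replicate, so it does not decide the question. The spike-in controls moved by a mean of 0.771 between these arrays, but such a mean does not measure a dye bias specific to a gene. Loss of the receptor and another effect of the MO2 sequence cannot be told apart at the median of 1.53 above 5m at 10 hpf, because a second morpholino and a rescue are not among the samples. Each may contribute.

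At 10 hpf, WT embryos stood apart from both injected samples, with hox and somitogenesis genes higher in both. An error of the WT array alone would also set WT apart. The hypothesis that the WT sample was at an earlier stage predicts a 5m minus WT median above 0.1 over genes that rise with age, and the 3768 probes that rose at least 2-fold in the MO2 channels gave 0.226 (SE 0.0103; 0.0111 at 5 hpf). It also predicts a median below -0.1 over genes that fall, and 4223 such probes gave -0.0776 (SE 0.00947). This part stays open, because an offset shrinks dim probes and an offset of 0 gave -0.130 (0.243 for those that rose). The SEs are across probes, which are not independent replicates. They hold no spread between samples, so how far these medians vary between samples was not determined. A bias with brightness also stays open: the correlation with the age gradient was at least 0.0904 in each brightness decile, but on the other arrays correlations within deciles reached -0.189. A lag may be part of the difference, and whether injection, clutch or time of collection set it stays open, as the samples do not separate them.

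Single probes differed 8-fold or more between 5m and WT in 48 pairs of probe and age, of which 23 were also 2-fold apart the same way at the other age. The MO2 channel of these probes differed by a median of 0.156 between the arrays of an age, but a flaw of the spot that scales both dyes cancels in the ratio, so that this value leaves spot flaws open. A difference in the amount of the whole transcript cannot be told from an effect at the probe's own sequence, since 42.1% of the other probes of these genes (8 of 19, exact 95% interval 20.3 to 66.5) went at least 2-fold the same way, next to 89.4% for genes 4-fold apart in MO2. The interval takes the 19 as independent, although probes of a gene and both ages were pooled, so it may be too narrow. The 89.4% comes from another rule, 4-fold on both arrays of an age, so the 2 shares are not alike. A sequence variant between clutches under a probe is a candidate explanation that was not tested, and no biological explanation was tested.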
